A study of Caenorhabditis elegans with 2 samples.

How the data were processed

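Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on early embryos of the nematode Caenorhabditis elegans, strain OP368, in 2 biological replicates of 1 group. Per the labels, the worms carry an additional, tagged copy of the T-box gene tbx-11 fused to EGFP, the chromatin was sonicated, and the sample description names an antibody against GFP for the pull-down, while the antibody field names tbx-11. The strain also carries an unc-119 rescue gene in an unc-119 mutant background. With 1 group, the design holds no contrast between conditions, and every comparison is between replicates or between peaks and the genome.

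The authors deposited peak lists on assembly ce11, 4 ranked lists of candidate peaks and 4 thresholded lists. Per the deposited file descriptions, the list of each replicate derives from the alignments of that replicate, and the pooled lists from the alignments of both, all against the same control alignments. The thresholded lists have 1 further input file whose nature is not given in the sources used here. The aligner, the peak caller, their versions and the read filters are likewise not given in the sources used here. The deposited signal value of a peak is the peak caller's own measure of its strength, never negative, with a scale that the sources do not state. It was used to describe and rank peaks within a list, to compare medians between classes of peaks of the same list, and to correlate ranks and log2 values between replicates. The deposited score of a peak expresses its irreproducible discovery rate (IDR, how consistently a peak ranks in a pair of analyses) on a scale up to 1000. All thresholded peaks had a score of at least 830. In the pooled ranked lists, 16 columns of values from unnamed sub-analyses were not used. The lists carry no read counts, so the depth of each library is unknown and the intervals given cover counting error over peaks or genes only. No mock pull-down list was analysed here.

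The main list was the conservative thresholded list of both replicates. Chromosome lengths, sequence and genes were taken from the same assembly with the Ensembl release 115 annotation, which has 19973 nuclear protein-coding genes, and the amino acid of each tRNA gene from the RefSeq annotation of the assembly. Gene starts are annotation starts, many of which are trans-splice sites in this animal. A promoter window ran from 1000 bp upstream to 500 bp downstream of a start. Mitochondrial peaks were left out of comparisons with the nuclear genome. Shares carry Clopper-Pearson 95% intervals. Shares of summits were compared with shares of the nuclear genome by the exact binomial test, two-sided. Replicate overlap required 1 bp and was compared with 1000 random placements of the peaks within their chromosomes, one-sided. Correlations of signal were tested with 100000 permutations of peaks. Gene lists were compared with all other protein-coding genes by the two-sided Fisher exact test. Motifs and all 6-base words were sought within 100 bp of the summit and of flank centres 500 bp to each side, with an exact binomial test on peaks that differed between summit and flank, and the larger p of the flanks was kept. Benjamini-Hochberg adjustment was applied over the classes of small RNA gene, the genome features, the 21 amino acid classes of tRNA gene, the 4 comparisons of signal between classes, the 6 chromosomes, the 18 gene lists, the 11 motifs or the 2080 words, with a threshold of 0.05.

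The gene lists, motifs, windows and tests were chosen before the data were examined. Genes were named by a rule fixed at the same time. It took the nearest gene start within 5 kb of the 15 strongest main-list peaks found in both replicates, up to 4 members of each list with a promoter summit by signal, tbx-11 and unc-119, and the 5 genes with the most summits in window or body. A summit counted as at a small RNA gene if it lay within 100 bp of a gene annotated as tRNA, snoRNA, snRNA, miRNA or ncRNA, assigned in that order. The ncRNA class is called other non-coding RNA genes below, and genes of any further annotated class were not sought. The comparison with small RNA genes was added after the peaks had been seen. So were the subset of peaks with no such gene, the control positions matched on GC content, and the small RNA genes and amino acids named.

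Alternatives chosen in advance were the other thresholded list, the main peaks at or above the median signal, each replicate alone, other windows, other overlap criteria, other T-box patterns and a random-position control. The word test was tested on 800 simulated peaks and recovered 18 of 20 planted words among 2080, with 0 calls before planting. These peaks were random positions, without the difference in GC content between summits and flanks that the real peaks had. The simulation therefore cannot show how many words are called because of that difference. The list test recovered 5 of 5 planted lists among 20, with 0 other calls. Its simulated genes received peaks independently, whereas neighbouring genes can share a peak in the real data. It therefore cannot show how many lists are called because of shared peaks. Of 100 sets of random positions, 4 passed the promoter test at 0.05. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.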

Results

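Binding of a GFP-tagged TBX-11, a T-box family DNA-binding protein, was mapped in early C. elegans embryos labelled as 1 hour old, in 2 biological replicates. The main list held 882 peaks, all nuclear, with a median width of 330 bp and a median signal of 103. The other pooled list held 1042 peaks and shared 740 summits with the main list. Replicate 1 alone gave 561 peaks and replicate 2 gave 467. Read depth is unknown, because the lists carry no counts. The signal is the authors' value for the strength of each peak, on a scale that is not stated.

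The replicates called largely the same places. Of 546 nuclear peaks in replicate 1, 356 (65.2%, 95% interval 61.0 to 69.2) overlapped a peak of replicate 2, and 343 of 467 peaks in replicate 2 (73.4%, 69.2 to 77.4) overlapped one of replicate 1. Random placement gave means of 0.260% and 0.287% (one-sided permutation p = 0.001 for each, the smallest that 1000 placements can give). Both replicates were called against the same control alignments. Signals at the 356 shared peaks ranked alike, with Spearman's rho of 0.781 and Pearson's r of 0.574 on log2 signal (permutation p = 1e-05 for both, the smallest that 100000 permutations can give). These correlations run across peaks, which are not independent replicates. They were higher at the 162 shared peaks at tRNA genes, with rho of 0.820, than at the 118 with no small RNA gene, with rho of 0.564, a difference that was not tested. With summits required within 200 bp, the values were 0.820 and 0.696. Of the main peaks, 345 (39.1%) overlapped a peak in both replicate lists and 328 (37.2%) overlapped none in either.

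The peaks concentrated at genes for small non-coding RNAs, a comparison chosen after the peaks had been seen. Genes for tRNAs, the adaptors of translation, lay within 100 bp of 238 of 882 summits (26.98%, 24.1 to 30.04), against 0.164% of the nuclear genome, a 164-fold excess (log10 of the one-sided exact binomial p = -441). Genes for snoRNAs, which guide chemical modification of ribosomal RNA, accounted for 60 peaks (6.80%, 58.9-fold, exact binomial adjusted p = 4.80e-83). With the summit required inside the gene, the snoRNA share was 0.113% and did not pass (exact binomial p = 0.341). Genes for snRNAs accounted for 14 peaks (39.1-fold, exact binomial adjusted p = 7.18e-18), and other annotated non-coding RNA genes for 56 (2.88-fold, exact binomial adjusted p = 6.43e-12). The 4 peaks at miRNA genes were 6.31-fold above the genome share (exact binomial adjusted p = 0.00406). The remaining 510 peaks (57.8%) had no gene of these classes within 100 bp, and further annotated classes were not sought. The tRNA share was 34.1% (30.1 to 38.2) in replicate 1 and 41.3% (36.8 to 45.9) in replicate 2.

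**Figure D1:**
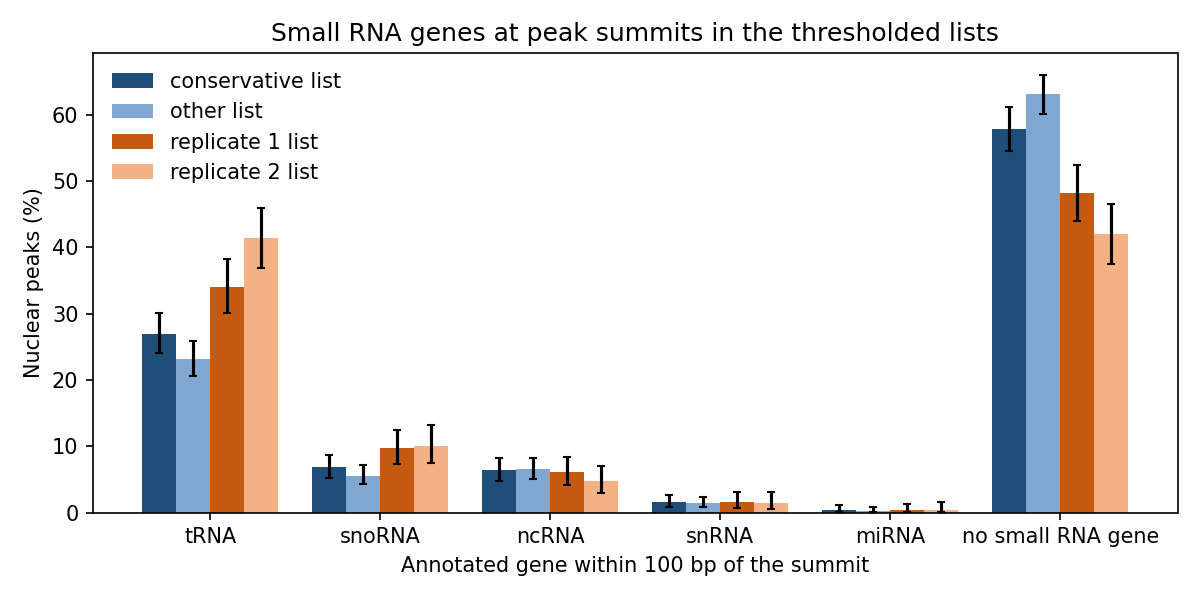
Percentage of nuclear peaks (vertical axis) whose summit lies within 100 bp of a gene of each class (horizontal axis), in the 4 thresholded lists. Bars show the share and error bars the Clopper-Pearson 95% interval; tRNA genes hold from 23.1% of the peaks in the other pooled list to 41.3% in replicate 2.

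Peaks at snoRNA and tRNA genes were stronger than those with no small RNA gene. Median signal was 257 at snoRNA genes and 150 at tRNA genes, against 89.1 at peaks with no small RNA gene, ratios of 2.89 and 1.69 (permutation test on ranks, adjusted p = 2e-05 for both). Peaks at snRNA and other non-coding RNA genes did not pass (ratios 1.32 and 1.03, permutation test on ranks, adjusted p = 0.29 for both). Those at miRNA genes, with a median of 181, were not tested. These comparisons cover the thresholded list, which lacks 120 ranked candidates past the score minimum, none at a small RNA gene, with a median signal of 172.7. Of the 15 strongest main peaks, 8 lay at snoRNA genes, 4 at tRNA genes and 1 at a miRNA gene. The strongest, on chromosome V from 12303474 to 12303805, had a signal of 973 in the main list, 554 in replicate 1 and 416 in replicate 2. It lay in an intron of frm-7, at the snoRNA genes C51F7.3 and C51F7.4. Next came the snoRNA gene W03C9.9 on chromosome II (11960670 to 11960974, intergenic, signal 788) and T03F7.8 in an intron of cutl-18 on chromosome V (11314046 to 11314381, signal 704). The tRNA genes among the 15 were a tRNA-Leu gene (WBGene00000308) and a tRNA-Lys gene (WBGene00014540), both in intergenic sequence of X, a tRNA-Ala gene (WBGene00014333) in an intron of him-4, and a tRNA-Cys gene (WBGene00022955) in an intron of cye-1, which encodes cyclin E. The miRNA gene was mir-51 on chromosome IV, with a signal of 518. The peaks with no small RNA gene among the 15 lay on chromosome III upstream of K12H4.5 (8043833 to 8044088, signal 600) and on chromosome II (5097542 to 5097760, signal 430), where C04G6.6 had the nearest start. Nearest protein-coding starts for the others were those of F55C5.17, W03C9.1, cutl-18, cye-1, sre-23, str-56, C04A11.5, col-181, hrg-5, T02E1.2 and Y43F8C.7, and 2 of the 15 had no start within 5 kb.

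Of the 612 nuclear tRNA genes, 244 (39.9%, 35.97 to 43.9) had a peak, as did 59 of 346 snoRNA genes (17.1%, 13.2 to 21.4). tRNA genes on X had a peak in 105 of 276 cases (38.04%) and those on autosomes in 139 of 336 (41.4%), with no detectable difference (Fisher exact p = 0.408). Of 21 amino acid classes, tRNA-Ala genes had the highest share among those with 20 or more genes (20 of 34, 58.8%), but no class passed after adjustment (Fisher exact, lowest adjusted p = 0.613), and 1 passed unadjusted. Many tRNA genes have identical copies, and reads that lie wholly within such copies cannot be divided between them. Among named non-coding genes, chosen after their values were seen, peaks lay at rpr-1, the RNA of RNase P (signal 296), at mrpr-1, the RNA of RNase MRP (signal 291), and at 4 of 5 srpr genes, which encode the RNA of the signal recognition particle. Of 30 sls genes for spliced leader RNAs, 3 had a peak (sls-2.1, sls-2.2 and sls-2.4), and none of the 12 smy genes did. The sls-1 genes lie close together on chromosome V, and whether reads can be placed uniquely there was not tested. Of the others looked up, 5 of 12 mir genes had a peak, 3 of them (mir-35, mir-36 and mir-37) the same one, against 6 of all 261 miRNA genes (2.30%), and yrn-1, tts-1, tts-2 and lin-4 had none.

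Summits favoured promoters. In the main list 384 of 882 summits (43.5%, 40.2 to 46.9) lay in a promoter window, against 26.4% of the nuclear genome (1.65-fold, exact binomial p = 5.68e-28). Among the 510 peaks with no small RNA gene the share was 266 (52.2%, 47.7 to 56.6; 1.98-fold, exact binomial p = 5.37e-35). Of those 266, 223 lay upstream of the nearest start, at a median of 190 bp from it. Of all 882 summits, coding exons held 5.67% against 24.6% of the genome (exact binomial adjusted p = 4.21e-50), UTRs 2.61% against 4.74%, introns 32.2% against 33.1% and intergenic sequence 59.3% against 37.3% (exact binomial adjusted p = 2.94e-39). Among the 510 peaks with no small RNA gene introns were depleted, with 24.7% (exact binomial adjusted p = 6.79e-05), and UTRs, with 3.53%, did not pass (0.2502).

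Promoter peaks were over-represented at histone and ribosomal protein genes and under-represented at chemoreceptor genes. Of 19973 protein-coding genes, 489 (2.45%) had a promoter summit, and 3 of 18 lists passed the test. Histone genes had one in 18 of 74 cases (24.3%, 15.1 to 35.7; odds ratio 13.3, Fisher exact adjusted p = 2.71e-12), although neighbouring histone genes share peaks and the 18 genes rested on 12 peaks. The strongest was shared by his-67 and his-68 (signal 174, 91.0 in replicate 1 and 65.4 in replicate 2), followed by one shared by his-59 and his-60 (signal 110), which was not in the list of replicate 2. Of the 12 histone peaks, 3 were in both replicates. By nearest start within 5 kb the histone odds ratio fell to 4.84 (Fisher exact adjusted p = 9.61e-04), and without replicate 2 it was 20.3. Genes for ribosomal proteins had a promoter summit in 14 of 83 cases (16.9%, 9.54 to 26.7; odds ratio 8.29, Fisher exact adjusted p = 1.17e-07), led by rpl-3 (signal 209), rpl-35 (184), rpl-20 (159) and rpl-15 (157), and 5 of the 14 peaks, these among them, were in both replicates. Assigned to the nearest start within 5 kb, ribosomal protein genes no longer passed (odds ratio 2.94, Fisher exact adjusted p = 0.0531). GPCR chemoreceptor genes had fewer, 10 of 1276 (0.784%, 0.376 to 1.44; odds ratio 0.300, Fisher exact adjusted p = 5.22e-05), with sre-23, sre-1, srh-269 and srd-44 the strongest, of which only the sre-1 peak was not at a small RNA gene. In replicate 2 alone this list did not pass (odds ratio 0.563, Fisher exact adjusted p = 0.496).

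Chaperone genes had a promoter summit in 4 of 36 cases (11.11%, 3.11 to 26.1) and narrowly missed the threshold (odds ratio 5.01, Fisher exact adjusted p = 0.0506). By nearest start the direction turned (odds ratio 0.782, Fisher exact adjusted p = 1.00). The 4 were hsp-60, a mitochondrial chaperonin (signal 136), cct-8, a cytosolic chaperonin subunit (105), hsp-3, an endoplasmic reticulum chaperone (97.5), and dnj-19 (92.9), whose peak lay at a non-coding RNA gene. No promoter summit lay at any of the 21 T-box family genes (upper 95% limit 16%), the 38 body wall muscle genes (9.25%), the 29 pharynx genes (11.9%), the 41 epidermis genes (8.60%), the 35 intestine genes (10%), the 59 neuron genes (6.06%), the 50 cell cycle genes (7.11%) or the 40 basic helix-loop-helix genes (8.81%), and lists of this size could show only large differences. The T-box genes tbx-11 and tbx-7 lie in a long stretch without candidate peaks, described below, whose cause is open, so their lack of a peak may not be informative. Early lineage regulators were represented by mex-1, an RNA-binding protein of the early embryo and also a germline list member (signal 91.0), and by ceh-13, a Hox gene (84.9), and neither peak was in either replicate's own list. These were also the only members with a summit among 60 germline and 91 homeobox genes. In the Wnt and Notch list 1 of 40 genes, mom-1, had a peak (388), at a tRNA gene. Nuclear hormone receptors had 3 of 274 (nhr-255, nhr-141 and nhr-47) and collagens 3 of 178 (col-85, col-185 and col-54), and neither list passed. The collagen peaks and that of nhr-255 lay at tRNA genes, and that of nhr-47, the same as for dnj-19, at a non-coding RNA gene. The genes with the most summits in window or body were kel-8 with 5 and W01D2.3, brd-1, cox-6B and mdt-26 with 3 each. These counts were not adjusted for gene length. The annotated cox-6B runs from 2699663 to 2786859 on chromosome III, and its strongest summit lay 69178 bp from the start. The strongest summits in kel-8 and brd-1 lay at tRNA genes inside the gene.

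**Figure D2:**
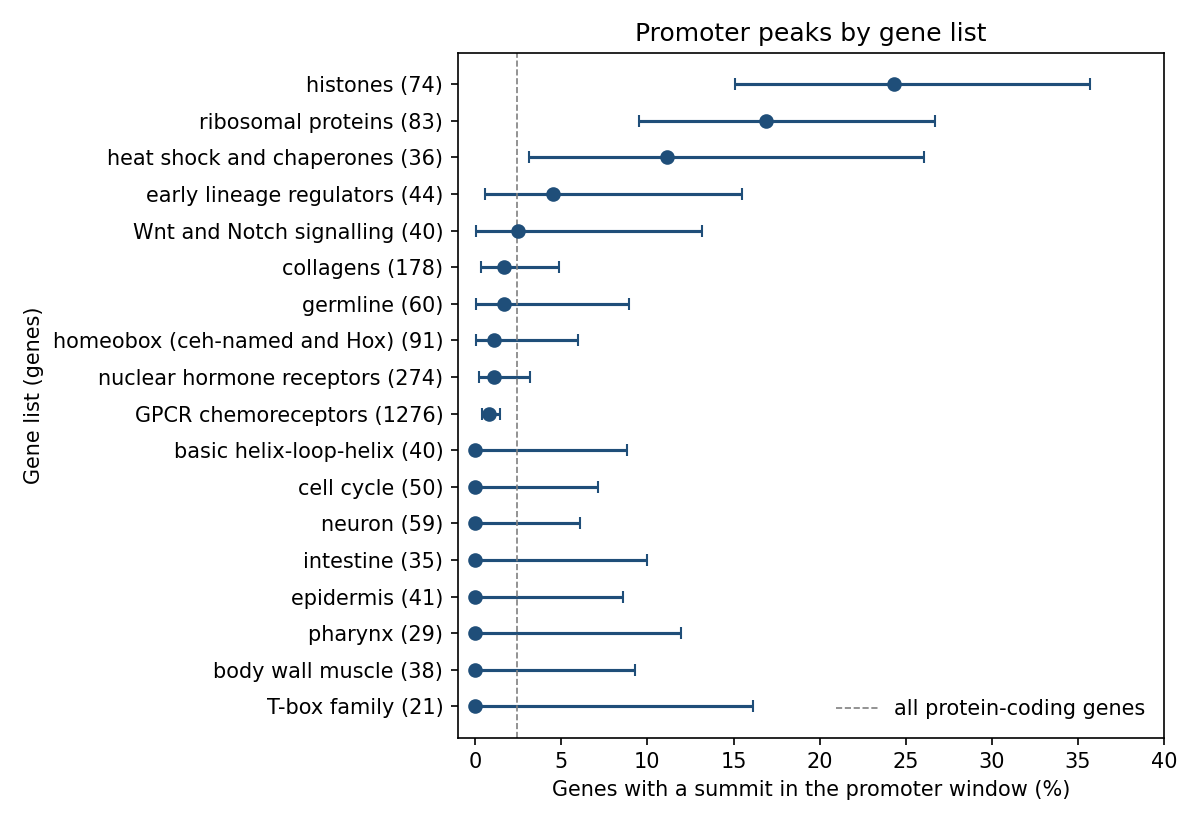
Percentage of each list's genes with a summit in the promoter window (horizontal axis), for the 18 gene lists (vertical axis, number of genes in parentheses). Points show the share, bars the Clopper-Pearson 95% interval and the dashed line the 2.45% of all protein-coding genes; histone and ribosomal protein genes lie above the line and chemoreceptor genes below it.

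Peaks were not spread over the chromosomes in proportion to length. X held 187 of 882 peaks (21.2%, 18.5 to 24.1) against 17.7% of the genome (1.2-fold, exact binomial adjusted p = 0.0288). X also carries 276 of the 612 tRNA genes (45.1%), and 103 of the 238 peaks at tRNA genes lay there. Among the 510 peaks with no small RNA gene the direction on X turned, with 58 peaks (11.4%, 8.75 to 14.5; 0.644-fold, exact binomial adjusted p = 7.20e-04). Chromosome III held more peaks than its length gives in both sets (1.21-fold and 1.40-fold, exact binomial adjusted p = 0.0288 and 0.00187). Chromosomes IV (0.845-fold) and V (0.837-fold) held fewer of all peaks (exact binomial adjusted p = 0.0498 and 0.0288), and neither passed among peaks with no small RNA gene (0.854-fold and 1.08-fold). In the lists of single replicates III, IV and V did not pass in either, and X did not pass in replicate 1 (1.19-fold, exact binomial adjusted p = 0.130). The middle 50% of the autosomes held 50.5% (46.7 to 54.3) of autosomal summits (exact binomial p = 0.820).

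**Figure D3:**
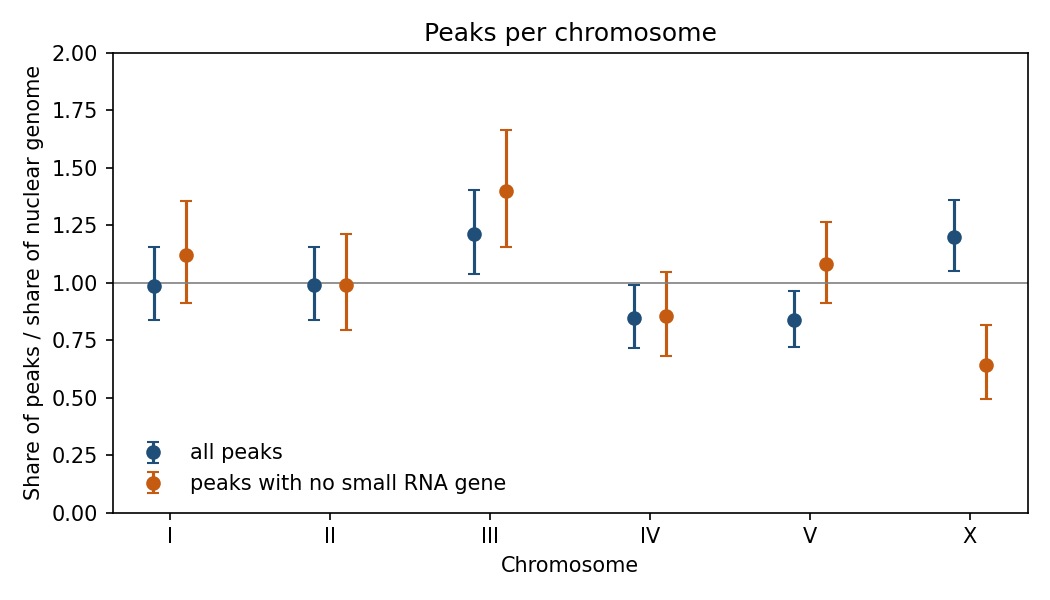
Share of peaks divided by share of the nuclear genome (vertical axis) for each chromosome (horizontal axis), for all 882 main peaks and for the 510 with no small RNA gene. Points show the ratio and bars the Clopper-Pearson 95% interval; X lies at 1.2 for all peaks and at 0.644 without small RNA genes.

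The T-box site GGTGTG, the core sequence bound by T-box proteins, lay within 100 bp of 85 of 882 summits (9.64%, 7.77 to 11.8) and in 4.195% and 4.99% of the left and right flanks (ratio 2.099, exact binomial p = 2.44e-04, adjusted 3.84e-04). Summits were richer in GC than flanks, 45.7% against 36.8% and 36.7%. The excess held within 50 bp of the summit (ratio 2.857, exact binomial p = 5.22e-04) and against random positions in the same feature class (ratio 2.125, exact binomial p = 5.27e-05). Against random positions matched on GC content, a control chosen after the data had been seen, it was not there (ratio 0.988, exact binomial p = 1.00). These positions were matched on GC content only, not on feature class. The longer pattern AGGTGTGA with at most 1 mismatch gave a ratio of 0.894 against the flanks (exact binomial p = 1.00). Among the 15 words made of the same bases as GGTGTG, its ratio ranked 7. Among the 441 main peaks with the higher signals and in replicate 2 alone the site did not pass (ratios 1.68 and 1.71, exact binomial p = 0.126 and 0.0919), nor did it among peaks with no small RNA gene (ratio 1.83, exact binomial p = 0.0640).

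The motif with the largest excess was the B box of tRNA genes, an internal promoter element for RNA polymerase III. It lay at 18.9% (16.399 to 21.7) of summits against 0.737% of flanks (25.7-fold, exact binomial adjusted p = 1.79e-43), and at 62.6% of the summits at tRNA genes. Of the 167 summits with a B box, 149 were at tRNA genes. Because the B box is part of tRNA genes, its excess restates the peaks there and is not separate evidence. tRNA genes without a peak were not compared for it. The GC box lay at 12.59% against 3.74% (exact binomial adjusted p = 1.06e-09) and GAGA repeats at 22.9% against 11.6% (5.73e-09). The AT-rich homeobox site was less frequent, 10.3% against 22.8% (8.54e-11), as was the GATA site, 31.0% against 42.2% (1.80e-06). The E2F site (3.29% against 1.304%, 0.0203) and CTGCGTC (5.10% against 1.81%, 4.22e-04) were more frequent, and the heat shock element (7.71% against 14.9%, 1.13e-04) and forkhead site (37.4% against 43.8%, 0.0362) less frequent. Among the 510 peaks with no small RNA gene the heat shock element, the forkhead site and the B box did not pass (exact binomial adjusted p = 0.0887, 0.356 and 0.0614). No difference was detected for E-boxes (53.3% against 52.3%, exact binomial adjusted p = 0.848). These motifs and all 6-base words were compared with the flanks, which are poorer in GC, and not with GC-matched positions. Of 2080 words, 426 were more frequent and 333 less frequent at summits. CGAACC, part of the B box and so not separate from the peaks at tRNA genes, led in all peaks (24.3% against 4.08%). In peaks with no small RNA gene 135 words were more and 126 less frequent, and CGCGCA led (20.8% against 2.84%).

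**Figure D4:**
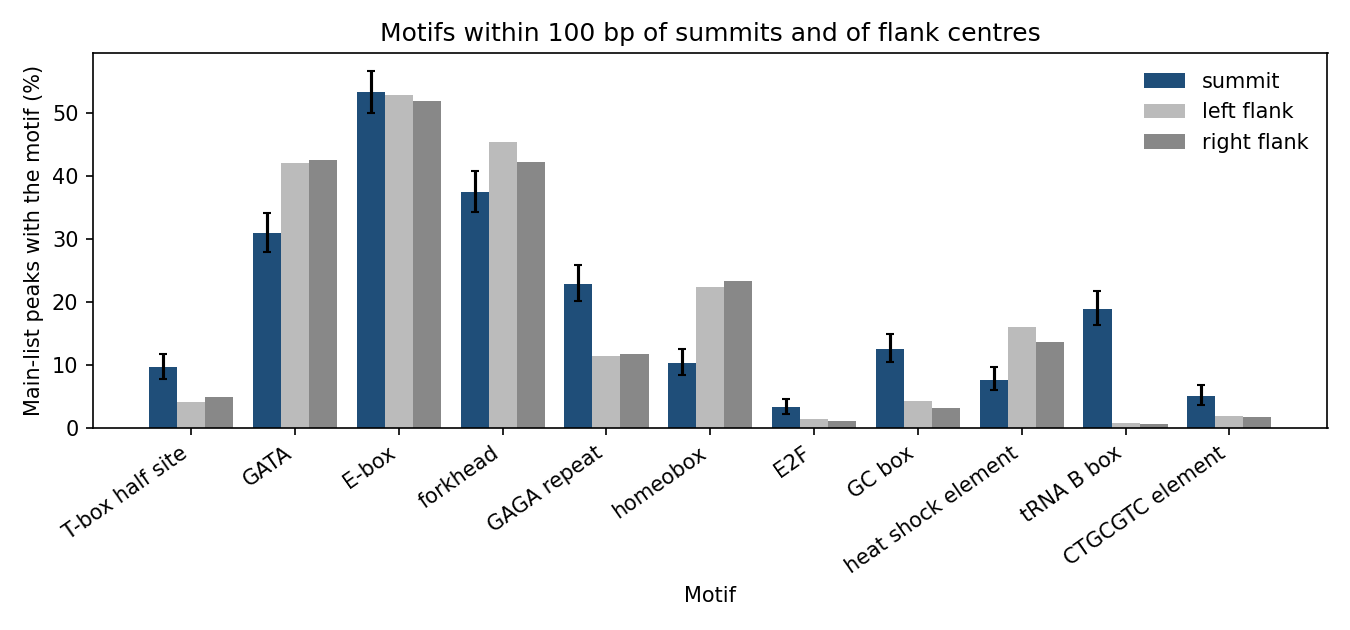
Percentage of the 882 main peaks (vertical axis) with each of 11 motifs (horizontal axis) within 100 bp of the summit or of the left and right flank centres. Bars on the summit carry the Clopper-Pearson 95% interval; the tRNA B box lies at 18.9% of summits and the T-box site GGTGTG at 9.64%.

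The loci of the transgene showed no thresholded peak. At tbx-11 (WBGene00006547, chromosome III, 6045615 to 6046981, minus strand) no candidate peak lay within 5 kb in any of the 8 lists. The surrounding stretch without a candidate summit measured 39114 bp in the conservative ranked list, from 6023243 to 6062357, and from 36341 to 42372 bp in the ranked lists. It spans 7 protein-coding genes, among them tbx-7, another T-box gene. At unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935, plus strand) the ranked lists held from 6 to 23 candidates within 5 kb, the strongest in the conservative ranked list with a signal of 47.4 at rank 6494 of 87796, and no thresholded list held any.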

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

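The tests of chance for the stretch at tbx-11, of the fosmid copies there, of the need for a T-box site at bound tRNA genes, of that site with identical tRNA sequences resampled together, and of the side of the weak peaks were chosen only after the result was seen.

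In the thresholded list of replicate 1, 15 mitochondrial peaks appeared (signal up to 928, and 8 of the 10 strongest peaks of that list), while replicate 2 and the pooled lists held 0. They drew attention because no comparison used them. Of the candidates in the conservative ranked list with a score of at least 830, 120 were not in the thresholded list, and they drew attention for the same reason. The strongest, on X from 15810938 to 15811210, had a signal of 3100, and 4 exceeded every peak of the main list. None of the 120 lay within 100 bp of a small RNA gene. The thresholded lists have 1 further input of unstated nature, and whether it removed these candidates was not tested, so the strongest peaks in the report are the strongest of the thresholded list.

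The peaks at tRNA genes were weighed against technical explanations and against the T-box site. Peaks at snoRNA, snRNA, miRNA and other non-coding RNA genes were not tested in this way. If reads shared between identical copies made all of these peaks, genes of unique sequence would have none, but 27.1% (19.98 to 35.3) of 140 such genes had one. This argues against such reads as the only source. The share was lower than the 43.6% of 472 repeated genes (odds ratio 0.481, Fisher exact p = 5.51e-04), the direction that sharing would give, so a partial contribution stays open. Uniqueness was judged on the whole gene sequence, so reads shared between near copies were not tested. Random positions matched on GC content lay at a tRNA gene in 0.340% of cases, against 26.98% of the main peaks. Because tRNA genes with their margins take up 0.164% of the nuclear genome, a low share was likely whatever the cause. The comparison shows only that GC content alone does not single out tRNA genes. It cannot decide whether base composition contributed to the peaks there. Whether the T-box site GGTGTG directs peaks to tRNA genes stays open. Its odds ratio at tRNA genes with a peak against those without was 2.43 (95% interval 1.05 to 5.84). This met the criterion set in advance, a lower limit above 1. However, the interval ran from 0.963 to 6.35 with the copies of each of 200 distinct sequences resampled together. At the summits of the 238 peaks at tRNA genes the T-box site did not pass against the flanks (ratio 1.70, exact binomial adjusted p = 0.400). Only 6.97% (4.11 to 10.9) of tRNA genes with a peak had it, so it cannot account for most. Open and highly transcribed chromatin that is recovered with any antibody stays open, since no mock pull-down was analysed here. With 1 group, no biological explanation other than the T-box site was tested.

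The stretch without candidates around tbx-11 was long for this genome. Of 10000 random positions, 0.410% (0.294 to 0.556) lay in a stretch as long in all 4 ranked lists, which argues against chance, although the gene was looked at because the strain carries its transgene. Of the 36-base words of the stretch, 98.5% occur once in the genome, which argues against reads that cannot be placed. A candidate explanation is that additional fosmid copies raise the control as much as the pull-down, but the control's depth is not in these lists, and the mean of 38.5 candidate summits in each flank of equal length cannot decide it.

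In the main list 33 weak peaks had a signal under the ranked median of 22.8, and each lay within 250 bp of a stronger peak, at a median distance of 203 bp, with a median score of 1000. All 33 lay on the higher-coordinate side (100%, 89.4 to 100), which argues against second binding sites, as these have no reason to favour a side. For 87.9% (71.8 to 96.6) the strongest overlapping candidate in both replicates had its summit nearer to the strong neighbour, short of the 90% set in advance. With a median peak width of 330 bp in this list, candidates of the neighbour can easily overlap the weak peak. A high share could therefore arise with or without a score taken over from the neighbour, and the share cannot decide it. Such a score may explain the weak peaks but stays open.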

How the results depend on the processing

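Peaks without small RNA genes, GC-matched positions, the small RNA distances and the removal of weak neighbours were chosen after seeing the data. Of 133 values under alternatives, 97 kept their direction and side of the threshold or stayed within 1.5 times, 17 lost the threshold, 10 changed direction and 9 counts moved further. Replicate overlap, signal rank, promoter share, histones and the tRNA share kept both under each alternative run for them. The histone odds ratio was 4.84 by nearest start, 8.28 in the upper part of the list by signal and 20.3 without replicate 2. The main peaks at or above the median signal number 441 by construction. They gave folds of 1.15 on III and 0.845 on IV, a T-box ratio of 1.68 and 221 less frequent words. In the other list chromosome I turned to 1.06 and the autosome middle to 49.5%. Without small RNA genes the folds were 1.12 on I, 0.854 on IV, 1.08 on V and 0.644 on X, the autosome middle 46.5%, the T-box ratio 1.83, and 135 words were more and 126 less frequent. The T-box ratio was 1.32 for GGTGTBR, 0.894 for AGGTGTGA with at most 1 mismatch and 0.988 against GC-matched positions. By nearest start, 1 list passed higher, with odds ratios of 2.94 for ribosomal proteins and 0.782 for chaperones. With the summit required inside the gene, the snoRNA share was 0.113% and no longer passed. With either replicate left out, peaks numbered 467 to 561, folds ran from 0.954 to 1.01 on I, 1.199 to 1.23 on III, 0.798 to 0.871 on IV, 0.821 to 0.825 on V and 1.19 to 1.297 on X, T-box ratios from 1.71 to 1.91, less frequent words from 203 to 238, depleted lists from 0 to 1 and chemoreceptor odds ratios from 0.241 to 0.563. Shorter lists have fewer peaks to test, and otherwise the cause was not tested. Read depth is unknown and its effect on weak peaks could not be assessed. No paired analysis was possible because there is 1 group.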

Other observations

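The position of the summit was described for 4 classes of small RNA gene after the data had been seen, and differences between classes were not tested. At tRNA genes 195 of 238 summits (81.9%) lay inside the gene, and the median position of all 238 was 21 bp downstream of the gene's start. At snoRNA genes 56 of 60 (93.3%, 83.8 to 98.2) lay upstream of the gene, at a median of 48.5 bp from its start, and 1 lay inside. At other non-coding RNA genes 45 of 56 summits (80.4%) lay inside, and at snRNA genes 7 of 14, with 3 upstream and 4 downstream.

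The strongest promoter peaks with no small RNA gene, also looked up afterwards, were led by chromosome III from 8043833 to 8044088 at K12H4.5 (signal 600). M01F1.9 (304) and K05C4.2 (290) were also single genes. Those in the windows of a pair of genes included chromosome III from 4568631 to 4568837 at mlcd-1 and idhg-1 (signal 401), chromosome III from 10461237 to 10461425 at atx-2 and ecps-1 (392), chromosome IV from 390376 to 390589 at ears-2 and uncp-18 (346), and chromosome I from 5176351 to 5176472 at npp-6 and spd-5 (267).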
